A study of Danio rerio with 9 samples.

How the data were processed

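Circular RNAs (circRNAs), closed RNA rings recognised by reads that cross a back-splice junction, were measured in the brain of zebrafish. There were 9 libraries in 3 groups of 3: fish with no toxication (control), fish labelled CYP and fish labelled CPF. The series names acute toxication with cypermethrin and chlorpyrifos. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made by standard Illumina methods. The dose, the exposure time, the number of fish behind a library and any batch are not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate fish, so p-values measure only the spread between these libraries, which may be technical.

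The deposited main table holds 2581 circRNAs in 9 libraries. Its sheet name calls the values fpm, and in the control and CYP columns the deposited values are RPM, junction reads per 1000000 reads of a library total set by the authors. The CPF columns hold the same deposited signal, except that 3 cells of dre_circ_2902, 1 in each library, had lost their decimal point and were restored with the point after the first digit. Each value was a whole multiple of the smallest value above 0 in its column, and the inverse of that step gave the library total. Of all values, 100% came out as whole reads at a tolerance of 1e-06, so the counts behind the deposited values could be recovered. No unused sample columns remained in the table. The aligner, the circRNA caller and the filter behind the table are not given in the sources used here. Per the submitters' processing notes, DESeq2 was used and UMD3.1 is named as genome build, with no role given. UMD3.1 is the name of a cattle assembly, and no coordinate is printed here. The circRNA numbers run up to 10372, so the table is a subset of a longer list. Of its circRNAs, 501 have 1 read in all 9 libraries together, so the subset was not made by a minimum of more than 1 read.

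For each pair of groups the authors also deposited a table of listed circRNAs with a value per group, a log2 fold change, a p-value and an adjusted p-value. Per the file headers the group values pool libraries 1, 2 and 3. Decimal points were lost in the values, in the log2 fold changes and in 4 small p-values. The digits of every listed value equalled a common constant times the pooled reads of the group plus 3, at a relative tolerance of 1e-09. With the point after the first digit, every log2 fold change matched the ratio of those sums within 0.001. The authors' fold changes therefore carry no correction for library totals.

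Recovered library totals, in units of 1000000 reads, ran from 68.74 to 94.7, and 22470 reads in all crossed a junction of a deposited circRNA. Junction reads of circRNAs that the authors' filter removed are not known. A count of 0 in a library allows up to 3 reads, or 0.0317 to 0.0436 RPM. Intervals (95%, Wilson for shares) and such limits cover counting error only, because PCR copies are not independent molecules. Folds given as "at least" take the reads of the other group as exact. Counting error in those reads and the spread between libraries can place the true fold lower. Libraries of a group were compared before averaging: a chi-square statistic per degree of freedom of 1.83 to 4.13 over the 9 pairs within groups showed no pair within sampling noise of each other.

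The main test was limma 3.58.1 with a mean-variance trend and empirical Bayes (R 4.3.3) on log2(RPM + 0.0126). The pseudocount was the median over libraries of the value of 1 read. Fold changes are on this scale. It can understate the change of low circRNAs, and can give a larger change than the ratio of means where a single library of the lower group is at 0. circRNAs above 0 in at least 3 of the 9 libraries were kept, which left 1158. All 9 libraries entered 1 fit, and p-values were adjusted by Benjamini-Hochberg at 0.05. On simulated reads with 50 circRNAs changed at each fold, drawn a single time per comparison, the procedure made no false calls. For CPF against control it called 0 of 50 at 2-fold, 0 at 4-fold, 9 at 8-fold and 16 at 16-fold. For CYP against control it called 0, 2, 3 and 11, and for CYP against CPF 0, 0, 1 and 8. Changed circRNAs that missed the filter count as not called. The simulated reads had a common dispersion and no shift of a whole group. They were less sparse than the real reads, with 1468 to 1483 circRNAs past the filter. Totals and numbers of circRNAs detected were compared by exact two-sided permutation tests of 3 against 3 libraries, on log2 values, whose smallest possible p is 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these.

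The tests, the groups, the rule for named circRNAs and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.00316 and 0.0506, no filter, a filter of 6 of 9 libraries, equal circRNA totals, quantile normalization, the replicate number as a block, no trend, a fit of the compared groups alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Those chosen after seeing the data were edgeR with library totals and no TMM, leaving out control 1 and CYP 1 together, thinning to equal circRNA reads with and without control 1, and totals over circRNAs with reads in both the control and CYP groups. The rule named, per comparison, up to 10 higher and 10 lower circRNAs past the threshold without overlap, by size of change. It then filled to 20 by smallest unadjusted p, and added the 5 higher and 5 lower with the smallest p in the authors' table and the 10 most abundant circRNAs. The files do not pair circRNA IDs with genes or coordinates, so only a few IDs per comparison are printed. For the same reason none of the 16 lists of host genes fixed beforehand was tested, and circRNAs were not summed per host gene.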

Results

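Back-spliced junction reads were counted in 9 zebrafish brain libraries: 3 untreated controls, 3 from fish given CYP toxication and 3 from fish given CPF toxication. The series names cypermethrin, a pyrethroid insecticide that acts on voltage-gated sodium channels, and chlorpyrifos, an organophosphate insecticide whose active form inhibits acetylcholinesterase. In units of 1000000 reads, library totals were 81.8 ± 11.8 in control, 76.2 ± 9.82 in CYP and 80.7 ± 11.2 in CPF (mean ± SD, n = 3 each). Of these, 1913 ± 282 reads per library crossed a junction of a deposited circRNA in control, 1769 ± 465 in CYP and 3808 ± 785 in CPF. The signal was sparse. Of the 2581 circRNAs in the table, 1005 (38.9%) were found in a single library and 54 in all 9. Correlations of log values across circRNAs, which are not independent replicates, were 0.229 to 0.458 between libraries of a group and 0.130 to 0.414 between libraries of different groups.

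Over the deposited circRNAs, brain libraries of the CPF group held more junction reads than those of either other group. The filter behind these circRNAs is not known, so the ratio over all circRNAs of a library may differ. Junction reads per 1000000 reads of the library (RPM) reached 47.2 ± 7.74 in CPF (SD, n = 3), against 23.4 ± 1.40 in control and 23.1 ± 4.24 in CYP. The CPF group was 2.0-fold above control (log2 ratio 1.0, SE 0.14), and every CPF library (41.4, 56.0 and 44.3 RPM) lay above every library of the other groups. The 95% counting interval of a single library was narrow beside this gap, at 40.1 to 42.7 for the lowest CPF library and 24.4 to 26.8 for the highest of the others. CYP and control could not be separated: the log2 ratio was -0.04 with an SE of 0.17. CYP 3 was the lowest library, at 18.2 RPM. Without CYP 3 the log2 ratio was 0.13 (SE 0.05), and CYP 1 and CYP 2 (25.5 and 25.6 RPM) lay above every control library. An exact two-sided permutation test gave p = 0.1 for CPF against control and for CYP against CPF, the smallest value that 3 against 3 libraries allow, and p = 1 for CYP against control. After Benjamini-Hochberg adjustment over the 6 exact tests of totals and detected numbers, the CPF comparisons stood at 0.15, so none passed.

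The higher CPF signal was spread over abundant and less abundant circRNAs. The 1158 tested circRNAs were divided into 4 classes by their mean over all 9 libraries. The filter and this mean include the CPF libraries, so a change can itself place a circRNA in the least abundant class, and the ratio of that class is no measure of how rare circRNAs changed. Summed RPM were 2.88-fold higher in CPF than in control in the least abundant class (log2 ratio 1.53, SE 0.42), 1.82-fold in the next (0.86, SE 0.22), 2.01-fold in the one above (1.01, SE 0.20) and 2.06-fold in the most abundant (1.04, SE 0.14). The 1423 circRNAs found in 1 or 2 libraries gave 1.83-fold (0.88, SE 0.33). In the most abundant class the values were 25.1 ± 4.28 RPM against 12.1 ± 0.660. CYP against control gave log2 ratios of 0.41 (SE 0.42), -0.10 (0.14), 0.10 (0.25) and -0.13 (0.19) in the same order, each smaller than its SE. The 10 most abundant circRNAs by mean RPM over all 9 libraries were all higher on average in CPF than in control. Of them, 4 had every CPF library above every control library, and 1 passed the test. That mean includes CPF, so a high CPF signal helps a circRNA into this set. The 10 most abundant circRNAs of each single library, which can differ between libraries, took 11.5 ± 0.880% of its circRNA reads in CPF and 12.6 ± 1.99% in control.

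**Figure D1:**
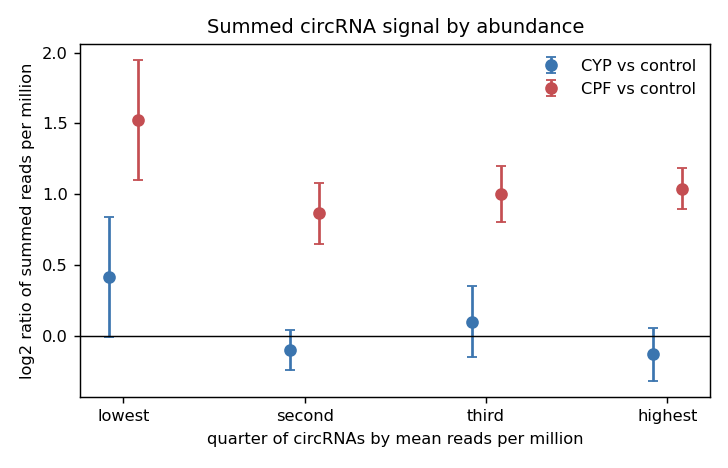
Log2 ratio of summed junction RPM (vertical axis) for 4 abundance classes of the 1158 tested circRNAs (horizontal axis), for CYP and CPF against control, 3 libraries per group; points are differences of mean log2 values and bars are SE. The CPF ratios run from 0.86 to 1.53 and the CYP ratios from -0.13 to 0.41; class membership rests on all 9 libraries, CPF included.

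More kinds of circRNA were also detected in CPF libraries. A CPF library held 1185 ± 67.9 circRNAs with at least 1 read, a control library 614 ± 125 and a CYP library 674 ± 79.6 (SD, n = 3). The CPF group was 1.96-fold above control (log2 ratio 0.97, SE 0.19), with no overlap of libraries; exact permutation p = 0.1, the smallest possible. CYP against control gave a log2 ratio of 0.15 (SE 0.21; exact permutation p = 0.6). Control 1 held the fewest, 470, with a low share of single-read circRNAs (12.6%) that CYP 1 had in part (25.1%). Without these 2 libraries, a check chosen after seeing the data, the log2 ratio of CPF to control was 0.79 (SE 0.05). In all, 680 circRNAs had reads in the CPF group alone, 273 in CYP alone and 239 in control alone, while 681 had reads in all 3 groups. At 1299 circRNA reads per library, these counts were 409.6, 368, 311 and 487 on average over 100 draws. Much of this followed from the larger number of CPF reads. With every library thinned to 1299 circRNA reads (a check chosen after seeing the data), CPF libraries held 685 ± 14.2 circRNAs, CYP libraries 600.5 ± 60.7 and control libraries 537 ± 101. The CPF group was then 1.29-fold above control (log2 ratio 0.37, SE 0.17), still without overlap, and 1.15-fold (log2 ratio 0.20, SE 0.03) without control 1.

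**Figure D2:**
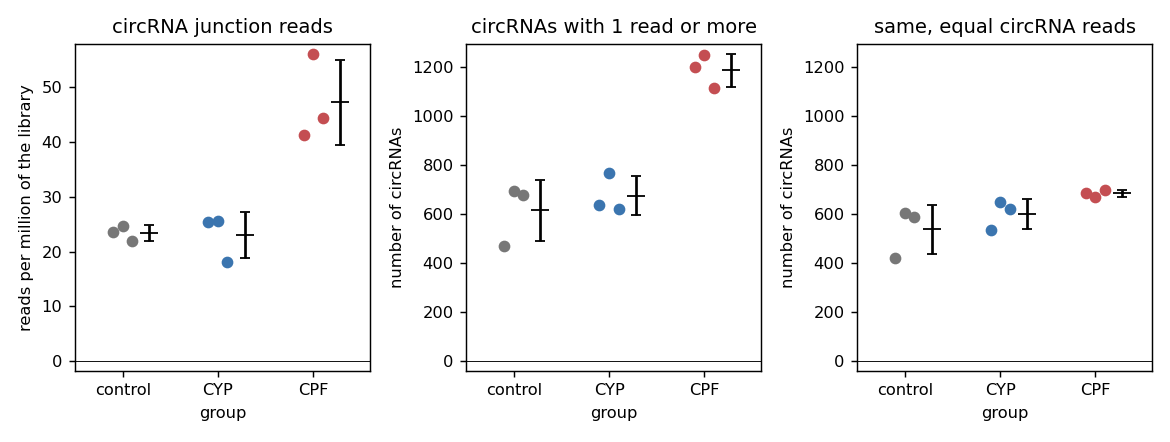
Summed junction RPM (left), number of circRNAs with at least 1 read (middle) and the same number after thinning each library to 1299 circRNA reads (right), by group; dots are the 3 libraries of a group and black bars the mean ± SD. The CPF libraries lie at 41.4 to 56.0 RPM and the other 6 at 18.2 to 25.6.

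In CPF against control, circRNAs shifted upward as a population and 5 passed the test singly. By limma, 5 circRNAs rose and 0 fell at an adjusted p under 0.05. Of the 1158 tested, 77.5% had a higher fitted value in CPF, and the median log2 fold change was 0.63. The filter counts the CPF libraries, so reads in CPF alone can bring a circRNA in. Without a filter, 66.3% of the 2581 circRNAs were higher in CPF and the median was 0.32. At an unadjusted p under 0.05 there were 194 higher and 10 lower, where 57.9 in all would come by chance; without CPF 2 the split was 118 and 4. CPF and control libraries did not overlap for 225 circRNAs (19.4%), 214 of them higher in CPF. Chance gives 10% for 3 against 3 libraries without ties, less where libraries tie at 0, and the other 9 divisions of these 6 libraries gave 50 to 121 circRNAs.

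The clearest single change was dre_circ_713, one of the 10 most abundant circRNAs by mean RPM over all 9 libraries, CPF included. It rose from 0.0980 ± 0.0874 RPM in control to 0.777 ± 0.313 in CPF (SD, n = 3), with 22 and 183 reads in all (8.43-fold in pooled RPM) and a CYP level of 0.175 ± 0.127. Its log2 fold change was 3.44 (SE 0.69; limma adjusted p = 0.0020; higher in 3 of 3 CPF libraries). Control 1 had 0 reads of it, and without that library the log2 fold change was 2.22. It was 4.14 without control 2. dre_circ_1917 was close to undetected in control, with 1 read in 3 libraries, and had 36 reads in CPF. It reached 0.150 ± 0.0259 RPM in CPF (log2 fold change 3.34, SE 0.79; limma adjusted p = 0.022). In the other direction dre_circ_9274 had 20 reads in control and 0 in CPF, at least 6.58-fold lower taking 3 reads over the CPF group as the limit. Of these reads 12 were in control 1, and without that library the limit was 4.29-fold. It missed the threshold (limma adjusted p = 0.070).

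These calls depended on the scaling and on single libraries. Rescaling the libraries to equal circRNA totals moved the median log2 fold change of all circRNAs from 0.63 to 0.24, and quantile normalization moved it to 0.03. Beside those medians the log2 fold change of dre_circ_713 was 2.57 and 2.38 and that of dre_circ_1917 2.65 and 2.64, and 0 circRNAs passed under either. The unadjusted split of 194 higher and 10 lower became 63 and 15 with equal totals, 33 and 39 with quantile normalization, 113 and 8 by edgeR with TMM and 23 and 10 by DESeq2. The count of 5 fell to 0 without CPF 3 and to 1 without CPF 2 and rose to 8 without control 2. It was 0 by edgeR with TMM, 0 by DESeq2, 0 with the compared groups alone and 0 with the smaller pseudocount.

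**Figure D3:**
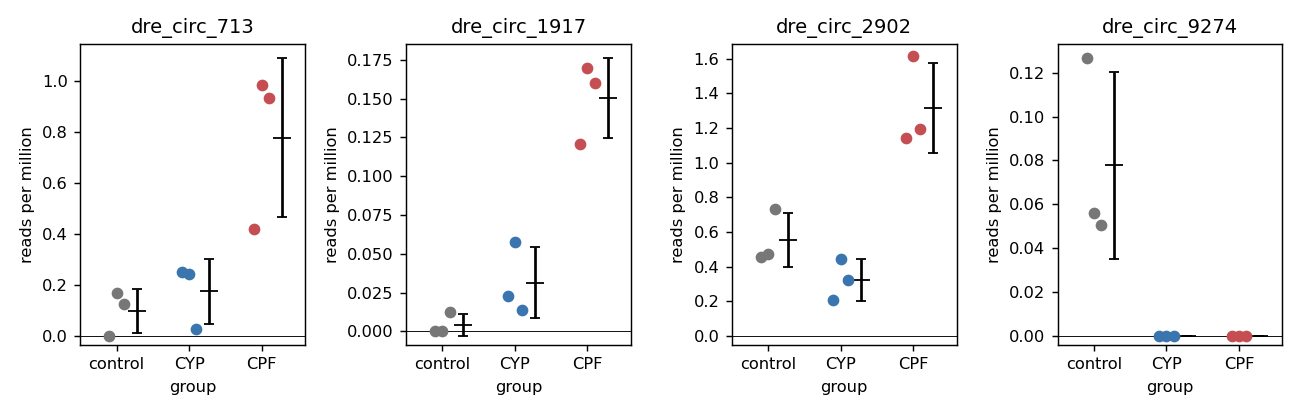
Junction RPM (vertical axes, each with its own scale) of 4 circRNAs by group; dots are the 3 libraries of a group and black bars the mean ± SD. dre_circ_713 and dre_circ_1917 rose in CPF against control, dre_circ_2902 was lower in CYP than in CPF, and dre_circ_9274 had reads in the 3 control libraries and none in the other 6.

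In CYP against control, no single circRNA could be called. limma gave 0 circRNAs at an adjusted p under 0.05 (smallest 0.273) and 75 at an unadjusted p under 0.05, 31 higher and 44 lower, against 57.9 by chance. The split was 52 and 25 without CYP 3, 34 and 21 without CYP 1 and 17 and 44 without control 1, and the total was 108 with equal circRNA totals and 47 with the compared groups alone or without CYP 2. edgeR with TMM and DESeq2 also gave 0, with 77 (42 higher, 35 lower) and 40 (27 higher, 13 lower) at an unadjusted p under 0.05. The median log2 fold change was 0.03, and libraries did not overlap for 79 circRNAs (6.82%, against 10% by chance without ties). The other 9 divisions of these 6 libraries gave 38 to 69. The circRNAs with the smallest p differed by presence and absence. dre_circ_1686 had 17 reads in CYP (0.0741 ± 0.0160 RPM, n = 3) and 0 in control, at least 6.08-fold higher taking 3 reads over the control group as the limit. dre_circ_9274 had 12, 4 and 4 reads in the control libraries and 0 in CYP, at least 6.21-fold lower, or 4.05-fold without control 1. dre_circ_2975 had 33 reads in control, 26 of them in control 1, and 0 in CYP, at least 10.2-fold lower, or 3.54-fold without control 1. Its log2 fold change was -2.80 (SE 0.80) with all libraries and -1.94 without control 1. All 3 missed the threshold (limma adjusted p = 0.273 for each). Of 50 simulated circRNAs changed at each fold, the test called 0 at 2-fold, 2 at 4-fold and 3 at 8-fold in this comparison.

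In CYP against CPF, circRNAs were lower in CYP as a population. This comparison shares its 3 CPF libraries with CPF against control and its 3 CYP libraries with CYP against control. The median log2 fold change was -0.60, and 212 circRNAs (18.3%) had no overlap between libraries, 201 of them lower in CYP, against 10% by chance without ties and 67 to 106 circRNAs in the other 9 divisions of these libraries. The filter counts the CPF libraries, and without it the median log2 fold change was -0.32. By limma, 0 circRNAs were higher and 1 lower in CYP at an adjusted p under 0.05, with 4 higher and 171 lower at an unadjusted p under 0.05. That split became 11 and 57 with equal circRNA totals, 34 and 29 with quantile normalization, 7 and 79 by edgeR with TMM, 7 and 5 by DESeq2 and 6 and 101 without CPF 2. The called circRNA was dre_circ_2902, the most abundant of the table by mean RPM over all 9 libraries, CPF included. It had 0.324 ± 0.120 RPM in CYP and 1.32 ± 0.259 in CPF (log2 fold change -2.03, SE 0.47; limma adjusted p = 0.036; lower in 3 of 3 CYP libraries). Its control level lay between, at 0.554 ± 0.155. The 3 CPF values of dre_circ_2902 are those whose decimal point was restored, so its CPF level and the call rest on that restoration. dre_circ_243 came next, with 9 reads in CYP and 81 in CPF, and missed the threshold (log2 fold change -2.71, SE 0.68; limma adjusted p = 0.066).

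The single call in this comparison was fragile. It was lost with equal circRNA totals (log2 fold change of dre_circ_2902 -1.01) and quantile normalization (-0.42), which moved the median of all circRNAs to -0.18 and 0.00, and the count was also 0 by edgeR with TMM and by DESeq2. It was 0 without control 3, CYP 1, CYP 3, CPF 1, CPF 2 or CPF 3, 2 without control 2 and 4 without control 1.

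Presence and absence also differed between groups, and for CPF much of this followed from the larger number of reads. There were 100 circRNAs with reads in all 3 CPF libraries and in no control library, and 3 in the opposite direction. For CYP against CPF the counts were 83 found in CPF and 3 found in CYP, and for CYP against control 19 found in CYP and 20 in control. The other 9 ways of dividing the same 6 libraries gave at most 47 circRNAs for CPF and control, 39 for CYP and CPF and 29 for CYP and control. At 1299 circRNA reads per library, a check chosen after seeing the data, the average counts over 100 draws were 26.9 in CPF and 8.84 in control, 18.4 in CPF and 9.77 in CYP, and 17.0 in CYP and 13.8 in control. In total these were 35.7 for CPF and control, 28.2 for CYP and CPF and 30.8 for CYP and control. Other divisions were not counted on thinned reads. Most circRNAs present in 1 group of a pair alone rested on few reads. When more than 2 reads were required in each library, 4 circRNAs remained in CPF and 1 in control for CPF and control. Over CPF and control, CYP and CPF, and CYP and control, the real divisions then gave 5, 4 and 3. The other divisions gave at most 3, 2 and 2. With presence in 2 of 3 libraries the real divisions gave 378, 337 and 218, and the others at most 234, 229 and 213.

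The fold changes of both insecticides against control were correlated across the 1158 circRNAs (Pearson r 0.557, Spearman rho 0.509), with the same sign for 65.4%. Both use the same 3 control libraries. In 100 simulations of unchanged groups against shared simulated controls, r was 0.494 ± 0.0217 (SD), rho 0.471 and the same-sign share 66.9%. All libraries, controls included, were drawn with a common dispersion. Traits of single libraries, such as the zeros of control 1, were therefore not modelled. The observed covariance was 0.348 and the simulated one 0.224 ± 0.0138 (SD). The controls are too few to be split into sets of at least 2. Part of the excess may therefore come from the shared controls or from what the simulation leaves out. circRNAs are not independent replicates, and with 0 calls for CYP no overlap of calls could be counted.

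The authors' deposited tables list 60 circRNAs for CPF against control (57 higher, 3 lower), 16 for CYP against control (6 higher, 10 lower) and 62 for CYP against CPF (all lower in CYP), 105 circRNAs in all. Every listed circRNA has an unadjusted p under 0.05 in those tables, while the smallest adjusted p in the authors' deposited table is 0.461, 1 and 0.146 in that order. The authors' deposited table for CPF against control gives dre_circ_713 a log2 fold change of 2.90, computed from pooled reads, and an adjusted p of 0.461. In the limma fit all 60, 16 and 62 circRNAs had the direction the authors' deposited tables give. At an adjusted p under 0.05 over all circRNAs tested, 5, 0 and 1 of them passed, and adjusted over the list alone 59, 15 and 59 passed. The lists were chosen on these samples, so neither the shared direction nor the count adjusted over the list alone is independent evidence. With equal circRNA totals, the counts adjusted over the list alone were 7, 16 and 0.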

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

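The tests with edgeR on library totals, with thinned reads, over circRNAs with reads in both control and CYP, and without control 1 and CYP 1 were chosen after the data were seen. Of 201 alternatives to the comparisons, 152 kept their side of the threshold or a similar size. The 152 include every alternative for the authors' lists, which were chosen on these samples. They also include every count of calls for CYP against control, which stayed at 0. The tally is therefore no measure of how stable the calls of the other comparisons were. Of the 201, 3 changed sign, all of them small differences between CYP and control. The log2 ratio of totals (-0.04) was 0.0015 without control 2 and 0.13 without CYP 3. The log2 ratio of detected numbers (0.15) was -0.03 without control 1. For CPF against control, the count of 5 circRNAs became 0 with the smaller pseudocount, equal circRNA totals, quantile normalization, the compared groups alone, edgeR with TMM and DESeq2, 1 by edgeR on library totals, 2 without a filter, 8 without the trend and without control 1 and CYP 1, 9 with the larger pseudocount and 15 with the filter of 6 of 9 libraries, and ran from 0 to 8 when each library was left out. For CYP against CPF, the count of 1 became 0 with equal totals, quantile normalization, no trend, the compared groups alone, both edgeR settings and DESeq2, and 3 with the larger pseudocount, the stricter filter and without control 1 and CYP 1, and ran from 0 to 4. CYP against control stayed at 0 in every alternative run. The stricter filter tests 350 circRNAs; the cause of the other changes was not tested. Left-out libraries leave 2 in a group, with the spread pooled over all. The log2 ratio of circRNAs detected was 0.37 for CPF against control (0.20 with control 1 also left out) and -0.19 for CYP against CPF when thinned, by construction from fewer reads. Ratios of totals and of detected numbers otherwise moved by less than 1 SD. Requiring more than 2 reads cut the circRNAs present in 1 group alone to 3 (CYP, control), 5 (CPF, control) and 4 (CYP, CPF), presence in 2 of 3 libraries gave 218, 378 and 337, and thinned reads gave 35.7 (CPF, control) and 28.2 (CYP, CPF). The correlation of CYP and CPF fold changes was 0.506 without a filter and 0.633 with equal totals, and 0.495 to 0.648 when each library was left out. Adjusted p ranged from 4.87e-05 to 0.999 for dre_circ_713, from 0.0050 to 0.761 for dre_circ_1917 and from 0.0026 to 0.990 for dre_circ_2902 over 22 alternatives each; they passed in 14, 13 and 8, with 0 changes of direction. The replicate block gave 0, 5 and 1 circRNAs for CYP against control, CPF against control and CYP against CPF, the same counts as without it, and changed no other call. Same-numbered libraries correlated at -0.06 to 0.11, above 0.1 for 1 of 9 pairs, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs. Restricting the authors' lists to adjusted p under 0.05 left 0 circRNAs; sums per host gene and tests of host gene lists were not run. Depth limits single circRNAs: 501 of 2581 have 1 read in all.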

Other observations

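Some circRNAs had reads in every library of 1 group and in no other library. In CPF, 32 circRNAs had reads in all 3 libraries and in none of the other 6, where the 81 sets of 3 libraries drawn from more than 1 group gave at most 16 (median 3). Control and CYP had 2 each, within the range of the mixed sets, 51 of which gave as many. dre_circ_9274 was one of the 2 in control, with 20 reads there and 0 in the 6 libraries of exposed fish. The count for CPF follows in part from its larger number of reads, and these counts were made after the data were seen.

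Of the tests below, those of library totals, of library preparation, of the 3-group division, over circRNAs with reads in both control and CYP, and with thinned reads were chosen after the data were seen. circRNA RPM was about 2.0-fold higher in the CPF libraries than in control. The library totals did not differ in that direction (log2 ratio -0.019), and the log2 ratio of circRNA RPM was 0.996 without the 10 most abundant circRNAs. Depth or a few circRNAs are therefore unlikely as the whole cause. Over circRNAs with reads in both the control and CYP groups, a selection that favours those groups, the log2 ratio was 0.86. That selection was made among the deposited circRNAs, and the filter behind them is not known. It can therefore not exclude a filter that kept circRNAs with a high CPF signal. Exposure stays open as a hypothesis: 10 of 280 divisions of the 9 libraries into groups of 3 gave a sum of squares as large as the real one (exact permutation p = 0.036), but these are the 10 that keep the CPF libraries together, so the value restates the separation already seen and decides nothing. Library preparation that differed between groups, such as how much ribosomal or linear RNA was left in a library, cannot be told apart from exposure, because 0 sample labels give a batch, date, lane or run.

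Control 1 and CYP 1 held few circRNAs with a single read: 12.6% of the circRNAs detected in control 1 (Wilson 95% interval 9.86 to 15.9%) and 25.1% in CYP 1 (21.9 to 28.6%), against 35.3 to 50.7% in the other 7 libraries. With all libraries thinned to 1299 circRNA reads the shares were 28.9% and 40.0%, still below the lowest of the other 7 at 49.8%, so library depth is unlikely as the cause. Fewer distinct molecules amplified to more reads could leave abundant circRNAs at 0: of those predicted at 5 reads or more from the other 8 libraries, 27.3% were at 0 in control 1, but 3.85% in CYP 1, below the 6.25% of CPF 2. That explanation stays open, with the test met by control 1 and not by CYP 1. No biological explanation was tested.

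Other divisions of the 6 libraries of each comparison were too few, at 10, for a share under 0.05. For CPF against control the real division gave 5 circRNAs and was the only 1 of 10 with as many, the highest of the others being 0. For CYP against CPF it gave 1, in 1 of 10 divisions, the highest of the others being 0. For CYP against control it gave 0, as did all 10. At an unadjusted p under 0.05 the real divisions gave 204, 175 and 75 circRNAs and the highest of the others 83, 50 and 59.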
